A study of Arabidopsis thaliana with 15 samples.

How the data were processed

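RNA was measured in closed flower buds of 5-week-old Arabidopsis thaliana plants (Col0 background) grown in long days. The 15 libraries fall into 5 genotypes of 3 libraries each: wild type (WT), the single mutants ref6-3 and ref6C, the double mutant elf6-3ref6C, and the triple mutant elf6-3ref6Cjmj13G. Per the labels' protocols, column-purified total RNA was made into libraries with a stranded total RNA kit and sequenced on an Illumina NextSeq instrument. The groups and replicate numbers were taken from the sample titles. The labels number the replicates 1 to 3 in each genotype but do not say that they came from separate plants, so p-values measure only the spread between these libraries, which may be technical. The labels give no sequencing batch.

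The authors deposited one table with 33323 genes. It holds whole-number counts per gene and library, deposited without normalization, and FPKM values that the file headers attribute to RSEM. It also holds the authors' own statistics, a log2 fold change with its p-value and adjusted p-value for each mutant against WT. The deposited log2 fold changes are named with the wild type first, and by their values they are WT over mutant; their sign was turned here. Per the file headers, ref6C replicate 3 was left out of the authors' statistics. The submitters' processing notes name STAR, RSEM 1.2.22, DESeq2 and the genome build TAIR10, with no role, order or settings; how reads shared between genes were treated and whether strand was used in counting is not given in the sources used here. The tests had been laid out for RSEM expected counts that would be rounded; the deposited counts were already whole, so the same test was run on them as they stand. Whether they are rounded RSEM estimates is not given in the sources used here. The deposited FPKM values were looked at but not used for any result.

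Total counts per library lay between 26009591 and 34140165. Replicates of a group had squared count differences of 1.41 to 2.81 times those of Poisson sampling (chi-square over its degrees of freedom), so no 2 libraries agreed within sampling noise and each was counted as its own replicate. Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, trended dispersion, TMM normalization, filterByExpr by group), with all 15 libraries in 1 fit so that the 5 groups shared an estimate of the spread. The filter kept 22411 genes, which held at least 99.88% of the counts of each library, the lowest share being that of ref6C replicate 3. The biological coefficient of variation was 2.51% (common dispersion 0.000628), which is low and makes small differences pass the test. For that reason the number of genes that also changed at least 2-fold is given for each comparison. Counts of list members and of overlaps are of any size unless a 2-fold limit is named. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes. Expression levels are TMM-normalized CPM, as mean ± SD over 3 libraries; log2 fold changes are given ± SE, the absolute fold change over the square root of F. There were 7 comparisons: each mutant against WT, ref6C against ref6-3, elf6-3ref6C against ref6C, and elf6-3ref6Cjmj13G against elf6-3ref6C. Against a group with no count in any library a fold is given as a lower bound, with 3 counts over the whole group as the floor; such floors cover counting error only.

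Gene lists were fixed before the data were examined: the targeted demethylases, other JmjC-domain genes, Polycomb group, floral MADS-box, flowering time, boundary and meristem, organ polarity and growth, gynoecium development, anther and tapetum, mature pollen, jasmonate, brassinosteroid, auxin synthesis and transport, seed maturation, heat stress, senescence, salicylate and defence, photosynthesis in green tissue, and circadian clock. Of 311 members written, 306 were kept; 5 were left out because the reference gives their identifier another symbol. The 18 lists other than the demethylases were tested in each of the 7 comparisons with camera (limma 3.58.1, on log2-CPM with a prior count of 2, preset correlation 0.01) against all other tested genes, and adjusted over the 126 tests. The test was repeated with a correlation estimated from the data. Each list also has the number of its members called over all genes tested and the number when adjusted over the list alone.

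The genes named in the text were chosen by a rule fixed before the data were examined. It takes REF6, ELF6 and JMJ13 in every comparison. It takes the 5 genes with the largest positive and the 5 with the largest negative log2 fold change in comparisons with WT, and 4 and 4 in the others. Those genes had to be called, nuclear, at a mean log2-CPM of at least 1, and without overlap between the libraries of the compared groups. From each list it takes up to 3 called members with the smallest adjusted p in a comparison, and list members that were not called may be given with their values. Gene names, neighbours and sequences came from the TAIR10.1 reference annotation, whose build name differs from the TAIR10 of the processing notes, so no coordinates are given; 32835 of the 33323 identifiers matched and 10950 had a symbol. Genes that overlap a gene on the opposite strand, among them JMJ13, ELF6, MYB21, MYB24, MRD1, STP9, AMS, FLC, ABCG26, LHCA4, CAB1, LNK2, RVE1, BOA, SHP1, AS1, CRC and ALC, cannot be separated from their partner, because the strand setting of the counting is not given in the sources used here. AT3G53140 and AT2G01008 overlap a gene on the same strand, and CPuORF31 has no entry in the annotation used; their values are uncertain.

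Overlaps between comparisons that share the WT libraries were set beside the overlap of independent lists and beside 20 simulated sets of unchanged groups. In each set ref6-3, ref6C and a WT group shared by them were all drawn from the WT means, each gene on its own. The tests were run first on simulated data: in a simulation of ref6-3 against WT with 50 genes changed at each size, edgeR recovered 72% of changes of 1.2-fold, 94% of 1.5-fold and 100% of 2-fold and 4-fold over 22016 genes, and 8 of 191 calls were false (4.19%). DESeq2 1.42.0 recovered 66%, 94%, 100% and 100% over 22411 genes, with 2 of 182 calls false. Camera called the 1 changed list and 0 of 19 unchanged lists in the single simulated set. That set changed only genes with more than 50 expected counts, gave genes of like level the same spread and drew genes independently. Far fewer genes were changed than were called in the real data, so these rates may not carry over. Correlation between the genes of a list was not simulated. Alternatives tried were relative log expression size factors in place of TMM, DESeq2, no filter on low counts, a filter of 1 CPM in 3 libraries, a fit of only the compared groups, the replicate number as a block, the estimated correlation, and leaving out each replicate in turn. Leaving ref6C replicate 3 out of fits it takes no direct part in was added after the data had been seen. The block serves as an alternative only, since same-numbered libraries did not deviate together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining counts and the plots.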

Results

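The dataset measures transcripts in closed flower buds of WT and of mutants named for demethylases of histone H3 lysine 27. REF6, ELF6 and JMJ13 are JmjC-domain proteins that remove methyl groups set by the Polycomb system, which keeps developmental genes silent. The comparisons ask which bud transcripts change in REF6 mutants and whether 2 of them (ref6-3 and ref6C) alter the same ones. They also ask what adding elf6-3 and then jmj13G changes. Each of the 5 genotypes has 3 libraries. Total counts lay between 27106757 and 34140165 in WT, 26113603 and 28777299 in ref6-3, 27550895 and 29530251 in ref6C, 26009591 and 32989973 in elf6-3ref6C, and 27234656 and 32176229 in elf6-3ref6Cjmj13G. One library stood apart: ref6C replicate 3 had a count in 29547 genes, against 25055 to 25712 genes in the other 14 libraries.

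The transcripts of the targeted genes were lower in the genotypes named for them. REF6 (AT3G48430) was at 69.4 ± 1.9 CPM (SD, n = 3) in WT, 32.9 ± 1.4 in ref6-3, 36.3 ± 0.49 in ref6C, 36.9 ± 2.3 in elf6-3ref6C and 36.1 ± 1.7 in elf6-3ref6Cjmj13G. These are log2 fold changes of -1.08 ± 0.04, -0.94 ± 0.04, -0.92 ± 0.04 and -0.94 ± 0.04 (SE), with adjusted p-values of 1.0e-17, 1.9e-16, 4.2e-17 and 2.1e-17. ELF6 (AT5G04240) fell from 61.3 ± 0.70 CPM in WT to 2.53 ± 0.14 in elf6-3ref6C and 8.67 ± 1.0 in elf6-3ref6Cjmj13G, so that it was 1.76 ± 0.10 log2 units higher in the second of these than in the first (adjusted p = 3.2e-13). JMJ13 (AT5G46910) fell from 24.8 ± 0.54 CPM to 9.04 ± 0.40 in elf6-3ref6Cjmj13G. It was also lower, by less, where no mutation of it is named: 21.5 ± 0.19 CPM in ref6-3, 22.0 ± 0.99 in ref6C and 18.3 ± 0.46 in elf6-3ref6C. ELF6 was not called in ref6-3 (-0.02 ± 0.04, adjusted p = 0.71) and was slightly lower in ref6C (-0.11 ± 0.04, adjusted p = 0.022), a call that ended when any of 4 libraries was left out (adjusted p 0.053 to 0.066). ELF6 and JMJ13 each overlap a gene on the other strand, and a transcript level says nothing of the protein made from it.

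**Figure D1:**
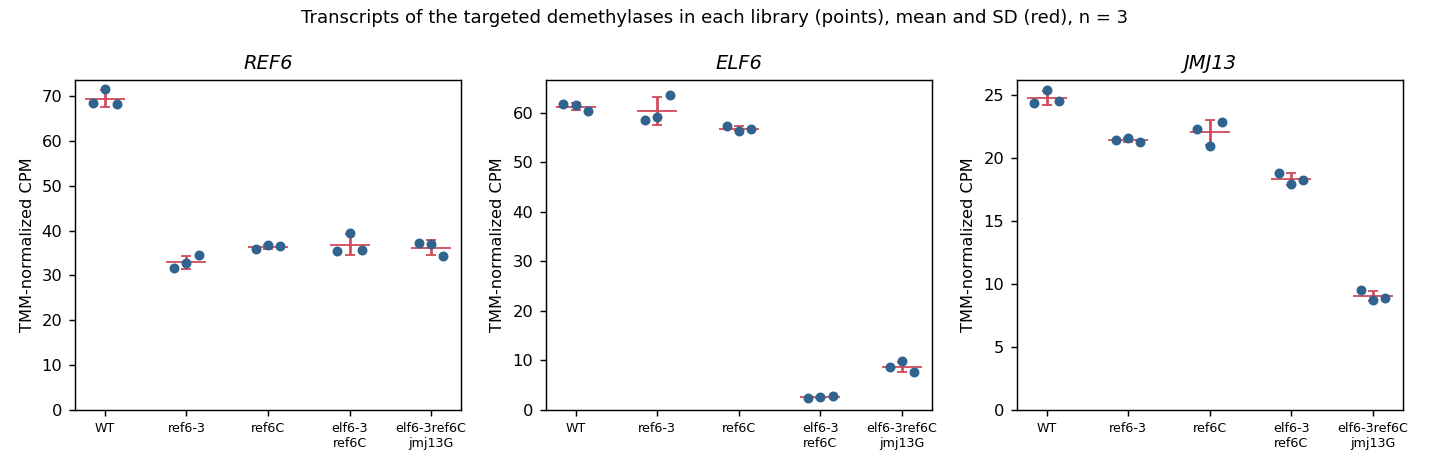
TMM-normalized CPM of REF6, ELF6 and JMJ13 in each library (points) with the mean and SD of each genotype (red, n = 3). Mean REF6 is between 32.9 and 36.9 CPM in the mutants, ELF6 at 2.53 and 8.67 CPM in the genotypes that carry elf6-3, and JMJ13 at 9.04 CPM in elf6-3ref6Cjmj13G.

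Falling transcripts outnumbered rising ones among the larger changes in every comparison with WT. In ref6-3, 152 genes were at least 2-fold higher and 1119 at least 2-fold lower than in WT. In ref6C the counts were 268 and 749, in elf6-3ref6C 843 and 2225, and in elf6-3ref6Cjmj13G 673 and 2260. With no limit on size, 3632 genes were higher and 4145 lower in ref6-3, 4131 and 4574 in ref6C, 7555 and 7804 in elf6-3ref6C, and 7167 and 7720 in elf6-3ref6Cjmj13G. Without ref6C replicate 3 these counts were 4101 and 3924 in ref6-3, 3507 and 4135 in ref6C, 7595 and 7842 in elf6-3ref6C, and 7543 and 7513 in elf6-3ref6Cjmj13G. The small excess of lower genes at any size thus turned round in ref6-3 and elf6-3ref6Cjmj13G with a library that is in neither. Leaving out ref6C replicate 3 gave 206 and 838 genes at least 2-fold higher and lower in ref6C, 164 and 1143 in ref6-3, 882 and 2277 in elf6-3ref6C, and 724 and 2278 in elf6-3ref6Cjmj13G. A filter of 1 CPM in 3 libraries, which tests fewer genes, left 95 genes at least 2-fold higher in ref6-3 and 159 in ref6C. No filter gave 571 in ref6C. With all libraries and the main filter, 34.7% of tested genes were called at any size in ref6-3, 38.8% in ref6C, 68.5% in elf6-3ref6C and 66.4% in elf6-3ref6Cjmj13G. The shares were 33.9% in ref6C against ref6-3, 61.2% in elf6-3ref6C against ref6C and 20.0% in elf6-3ref6Cjmj13G against elf6-3ref6C. Counts of called list members below are to be read beside these shares.

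**Figure D2:**
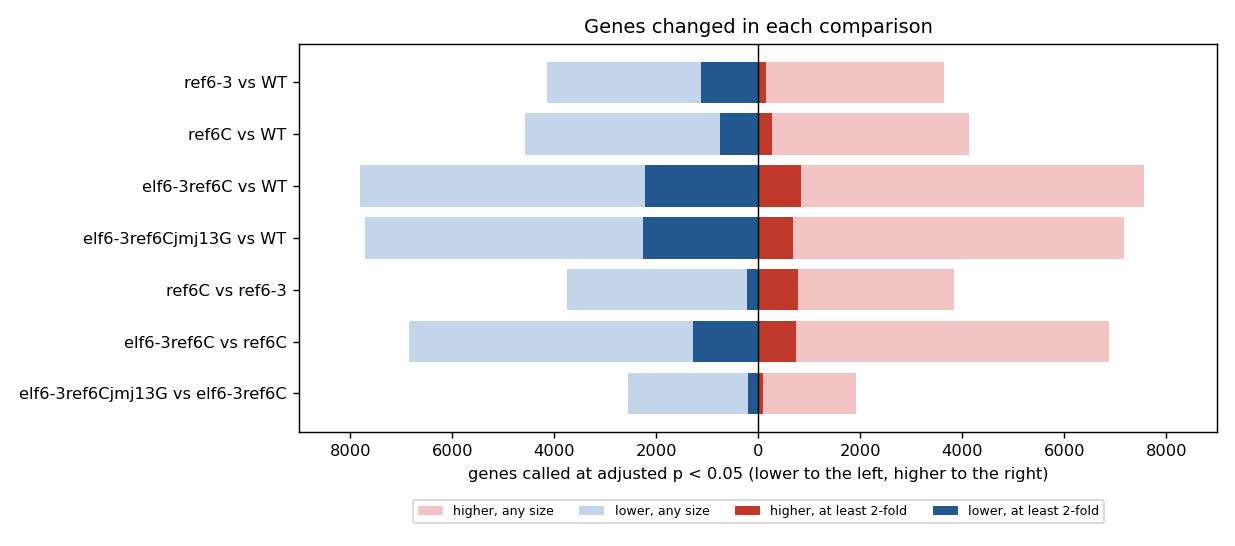
Number of genes called at an adjusted p below 0.05 in each comparison (horizontal axis, lower to the left and higher to the right of 0), of any size in pale and at least 2-fold in dark colours. Lower genes exceed higher ones in the dark bars of the comparisons with WT (1119 against 152 in ref6-3), and the last comparison has the smallest bars (94 higher and 197 lower).

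Buds of ref6-3 had far less transcript of genes used in mature pollen. Of the 18 measured genes of that list, 16 fell, 13 of them at least 2-fold, 0 rose and 2 were not called, with the same counts adjusted over the list alone (median log2 fold change -1.62). VGD1 (AT2G47040), a pectin methylesterase of the pollen tube, fell from 315 ± 2.9 to 83.8 ± 3.3 CPM (SD, n = 3). PPME1 (AT1G69940), another such enzyme, fell from 169 ± 10 to 42.7 ± 2.2, and the hexose transporter gene STP9 (AT1G50310) from 117 ± 1.3 to 40.4 ± 0.26. The list stood below other genes in the camera test (adjusted p = 1.2e-13, and 0.0016 with an estimated correlation). The anther and tapetum list, whose genes act before pollen matures, was not called (median -0.04, adjusted p = 0.61): 3 of 17 members rose and 4 fell, the same adjusted over the list alone. MS1 (AT5G22260), a regulator of tapetum development, fell by 0.41 ± 0.04, QRT3 (AT4G20050), which helps to separate pollen grains, fell by 0.29 ± 0.03, and the tapetal gene A9 (AT5G07230) rose by 0.24 ± 0.04.

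Jasmonate genes fell with the pollen genes in ref6-3. Of 25 measured members 16 fell and 1 rose (2 rose adjusted over the list alone), with a median of -0.25 (adjusted p = 5.2e-06, and 0.0071 with an estimated correlation). The steepest falls were in a pair of MYB factors that act downstream of jasmonate in stamens and petals. MYB21 (AT3G27810) went from 11.8 ± 0.56 CPM to 0.152 ± 0.18 (log2 fold change -6.18 ± 0.23, adjusted p = 5.7e-18) and MYB24 (AT5G40350) from 5.50 ± 0.29 to 0.0599 ± 0.054 (-6.40 ± 0.32, adjusted p = 2.3e-15). JAZ1 (AT1G19180), a repressor of jasmonate response, fell from 39.7 ± 1.6 to 22.5 ± 0.31 CPM. Both MYB genes overlap a gene on the other strand.

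Genes of young organs and green tissue were slightly higher in ref6-3. In the organ polarity and growth list 11 of 16 members rose and 1 fell, the same adjusted over the list alone (median 0.17, adjusted p = 0.0021, and 0.031 with an estimated correlation). ANT (AT4G37750), which promotes organ growth, rose from 124 ± 1.5 to 144 ± 2.2 CPM and the YABBY gene FIL (AT2G45190) rose by 0.23 ± 0.03, while INO (AT1G23420), a YABBY gene of the ovule, fell from 9.53 ± 0.75 to 6.44 ± 0.12. In the boundary and meristem list 8 of 13 members rose and 2 fell, the same adjusted over the list alone (median 0.31, adjusted p = 0.0052), among them the homeobox genes KNAT6 (AT1G23380) at 0.44 ± 0.05 and KNAT1 (AT4G08150) at 0.28 ± 0.04. The call was lost with an estimated correlation (adjusted p = 0.085). Of 21 photosynthesis genes 18 rose and 1 fell, the same adjusted over the list alone (median 0.22, adjusted p = 4.5e-08, but adjusted p = 0.30 with an estimated correlation). The light-harvesting gene LHB1B1 (AT2G34430) rose most in that group, from 28.8 ± 3.5 to 72.9 ± 4.0 CPM, and CAB2 (AT1G29920) rose from 594 ± 33 to 883 ± 37.

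Genes with a mean log2-CPM of at least 1 over all libraries and no overlap between the compared groups were ranked by fold change, which leaves out sparser genes that moved more. Within that limit, rises in ref6-3 were largest for MRD1 (AT1G53480), from 0.227 ± 0.042 to 39.4 ± 2.2 CPM (log2 fold change 7.40 ± 0.11, adjusted p = 1.1e-26), and for AT2G01422, a locus with no description, from 1.94 ± 0.13 to 73.5 ± 1.8. Smaller in amount were the rises of a peroxidase gene, AT2G38380 (3.32 ± 0.36), and of AT5G52940 (2.55 ± 0.25), whose product has a domain of unknown function. AT4G12735 had 0 counts in WT and was at least 2.99-fold higher in ref6-3, a call that ended without ref6-3 replicate 1 (adjusted p = 0.057). Within the same limit, which leaves out MYB24, the genes at the other end beside MYB21 were the beta-galactosidase gene BGAL13 (AT2G16730), from 8.95 ± 1.5 to 0.0868 ± 0.058 CPM, AT5G39880 (-4.94 ± 0.20), the F-box gene DAF1 (AT3G62230, -4.78 ± 0.13) and GLOX1 (AT1G67290, -4.74 ± 0.15), a glyoxal oxidase relative. Among flowering-time genes the MADS-box gene MAF5 (AT5G65080) fell from 7.91 ± 0.41 to 0.70 ± 0.16 CPM, while LFY (AT5G61850), which sets floral identity, rose by 0.65 ± 0.09. The senescence protease gene SAG12 (AT5G45890) had 0 counts in WT and was at least 50.1-fold higher in ref6-3, at 1.65 ± 0.37 CPM.

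In ref6C buds the genes of the anther and its tapetum fell together. Of 17 members 16 fell, 0 rose and 1 was not called, the same adjusted over the list alone (median -0.37, adjusted p = 4.6e-11, and 0.0016 with an estimated correlation). MS2 (AT3G11980), which makes fatty alcohols for the pollen wall, fell from 395 ± 13 to 198 ± 7.5 CPM (SD, n = 3). MS1 fell from 32.7 ± 0.37 to 16.4 ± 0.82, and ABCG26 (AT3G13220), an exporter of pollen wall precursors, from 148 ± 3.7 to 93.8 ± 2.9. Mature pollen genes fell less evenly: 13 of 18 were lower and 0 higher, the same adjusted over the list alone, with a median of -0.32 (adjusted p = 2.6e-06, and 0.0082 with an estimated correlation). The sugar transporter gene STP11 (AT5G23270) went from 1.88 ± 0.074 to 0.046 ± 0.019 CPM, the pollen gene BCP1 (AT1G24520) from 2.65 ± 0.57 to 0.185 ± 0.073, and the receptor kinase gene BUPS1 (AT4G39110) from 14.3 ± 0.81 to 7.37 ± 0.21.

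Other groups did not move as lists in ref6C. Of the 25 jasmonate genes 7 rose and 11 fell (8 and 12 adjusted over the list alone; median -0.04, adjusted p = 0.97). The storage protein genes VSP2 (AT5G24770) and VSP1 (AT5G24780) rose by 0.38 ± 0.02 and 0.35 ± 0.02, and the lipoxygenase gene LOX3 (AT1G17420) fell by 0.55 ± 0.05. Salicylate and defence genes went both ways, 4 up and 6 down of 13 (the same adjusted over the list alone, adjusted p = 0.61). WRKY70 (AT3G56400), a regulator of salicylate response, fell from 31.8 ± 0.96 to 19.3 ± 0.60 CPM, and the glucanase gene PR2 (AT3G57260) rose from 0.538 ± 0.19 to 2.48 ± 0.52. MAF5 rose from 7.91 ± 0.41 to 19.1 ± 1.4 CPM. The xyloglucan endotransglucosylase gene XTH22 (AT5G57560) fell from 6.48 ± 0.66 to 1.28 ± 0.19, and SAG12 was at least 109-fold higher than in WT, at 3.57 ± 0.51 CPM.

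In ref6C, the genes at the top of the ranking within the expression limit included AT2G38380 (5.42 ± 0.26, adjusted p = 1.6e-15). A transposable element gene, AT5G35935, rose from 0.299 ± 0.056 to 8.70 ± 0.40 CPM, and AT4G12735 was at least 7.29-fold higher than in WT. AT3G41762 and AT2G01008 were also among them, but ref6C replicate 3 decided their size: AT3G41762 was at 1.533, 1.014 and 20.208 CPM and AT2G01008 at 1.703, 1.284 and 35.707 CPM in replicates 1, 2 and 3. Without that library their log2 fold changes were 2.14 and 1.16 in place of 4.69 and 4.25. At the bottom of the ranking within that limit, which leaves out STP11 and BCP1, were AT3G28770 (-4.48 ± 0.12), BGAL13 (-3.81 ± 0.20), AT5G39880 (-3.69 ± 0.16), a major facilitator gene, AT1G72130 (-3.66 ± 0.16), and AT3G05610 (-3.65 ± 0.15), described as a member of the invertase and pectin methylesterase inhibitor superfamily.

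The REF6 mutants shared part of their changes. Of the genes called in ref6-3 and in ref6C, 1807 rose in both and 2225 fell in both. Independent lists would share 669 and 846. Another 589 genes were called in opposite directions. Among changes of at least 2-fold, 446 genes fell in both (37.4 for independent lists) and 75 rose in both (1.82). Comparisons with the same WT libraries are tied by chance. Simulated unchanged groups shared 0.60 calls on average and 3 at most. They gave a correlation across genes of 0.494 on average and 0.560 at most, against the observed 0.684. The covariance of the fold changes was 0.262, and 0.00919 in the simulation. WT was drawn anew there and each gene on its own, so a joint deviation of the real WT libraries is not in it. WT has 3 libraries and could not be split into sets of 2 for each mutant, so part of the excess may come from the shared controls; genes are not independent replicates.

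Set against each other, ref6C buds had more mature pollen transcript and less anther transcript than ref6-3 buds. Of 18 mature pollen genes 12 were higher in ref6C and 1 lower, the same adjusted over the list alone (median 0.90, adjusted p = 5.0e-07, and 0.0065 with an estimated correlation). VGD1 was at 258 ± 4.2 CPM in ref6C against 83.8 ± 3.3 in ref6-3 and PPME1 at 133 ± 3.6 against 42.7 ± 2.2 (SD, n = 3). Of 17 anther and tapetum genes 16 were lower in ref6C and 0 higher, the same adjusted over the list alone (median -0.47, adjusted p = 4.6e-11, and 0.0016 with an estimated correlation). There MS2 was at 198 ± 7.5 against 369 ± 5.6 CPM and CYP703A2 (AT1G01280), a hydroxylase of pollen wall synthesis, at 73.7 ± 1.8 against 119 ± 2.3. In the jasmonate list 18 of 25 genes were higher and 2 lower, the same adjusted over the list alone (median 0.23, adjusted p = 1.5e-06, and 0.0059 with an estimated correlation). MYB21 was at 4.60 ± 0.52 CPM against 0.152 ± 0.18.

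Several smaller group differences separated the REF6 mutants as well. Photosynthesis genes were lower in ref6C, 18 of 21 with 0 higher, the same adjusted over the list alone (median -0.24, adjusted p = 4.0e-08, but adjusted p = 0.30 with an estimated correlation). LHB1B1 was at 18.9 ± 1.7 against 72.9 ± 4.0 CPM. Of 17 floral MADS-box genes 8 were higher and 1 lower, the same adjusted over the list alone (median 0.07, adjusted p = 0.036, but adjusted p = 0.23 with an estimated correlation). The carpel gene SHP1 (AT3G58780) was at 38.9 ± 1.9 against 27.7 ± 0.85 CPM. That call ended under several other settings, which include leaving out ref6-3 replicate 1 (adjusted p = 0.103) or ref6C replicate 1 (0.065). Senescence genes were higher, 8 of 15 with 0 lower, the same adjusted over the list alone (median 0.13, adjusted p = 0.027, but adjusted p = 0.20 with an estimated correlation). This call ended without ref6C replicate 3 (0.088) or ref6-3 replicate 2 (0.061). SAG13 (AT2G29350) was at 3.45 ± 0.40 against 0.452 ± 0.18 CPM.

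At the ends of the ranking within the expression limit, MRD1 was lower in ref6C than in ref6-3, with a log2 fold change of -6.20 ± 0.10 (0.532 ± 0.052 against 39.4 ± 2.2 CPM), and AT2G01422 had a log2 fold change of -3.69 ± 0.06. FTM1 (AT1G43800), a fatty acid desaturase gene, and SEN1 (AT4G35770), a gene induced by darkness, were lower too (-3.58 ± 0.21 and -3.40 ± 0.13). In the other direction, AT5G35935 was at 8.70 ± 0.40 against 0.0482 ± 0.018 CPM and MAF5 at 19.1 ± 1.4 against 0.70 ± 0.16 (log2 fold change 4.77 ± 0.13, adjusted p = 1.9e-21). From the brassinosteroid list, the expansin gene EXPA8 (AT2G40610) was at 30.3 ± 0.87 against 10.1 ± 0.27. AT2G01008 was at the top of the ranking only through ref6C replicate 3: its log2 fold change was 3.91 with that library and 0.81 without it. In all 3844 genes were higher and 3759 lower, 782 and 222 of them at least 2-fold. Without ref6C replicate 3 the counts were 3119 and 3539, with 701 and 264 at least 2-fold, so the balance at any size turned round. With all libraries it also turned round with relative log expression size factors (3670 and 3933), DESeq2 (3022 and 3253) and no filter (3693 and 4091). REF6 itself was 0.14 ± 0.05 higher in ref6C (adjusted p = 0.018), a call that ended when any of 4 libraries was left out (0.053 to 0.099).

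Buds of elf6-3ref6C had less mature pollen transcript than WT. Of 18 mature pollen genes 16 fell and 0 rose, 14 of the 16 at least 2-fold and the same adjusted over the list alone (median -2.12, adjusted p = 9.7e-08, and 0.0059 with an estimated correlation). VGD1 was at 66.8 ± 1.1 CPM (SD, n = 3) against 315 ± 2.9 in WT, PPME1 at 31.8 ± 0.72 against 169 ± 10 and STP9 at 29.5 ± 1.8 against 117 ± 1.3. Anther and tapetum genes fell in 15 of 17 cases and rose in 0, the same adjusted over the list alone (median -0.83, adjusted p = 5.0e-07, and 0.0059 with an estimated correlation). QRT3 was at 67.2 ± 1.5 against 159 ± 4.1 CPM and MS2 at 191 ± 0.73 against 395 ± 13. Of 25 jasmonate genes 20 fell and 3 rose, the same adjusted over the list alone (median -0.55, adjusted p = 0.00023, and 0.018 with an estimated correlation). The repressor genes JAZ9 (AT1G70700) and JAZ6 (AT1G72450) fell by 0.98 ± 0.03 and 0.77 ± 0.03.

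Defence genes rose in elf6-3ref6C. Of 13 members 10 rose and 0 fell, the same adjusted over the list alone (median 0.61, adjusted p = 0.00034, but adjusted p = 0.089 with an estimated correlation). PR2 was at 33.6 ± 1.5 CPM against 0.538 ± 0.19 in WT (log2 fold change 5.93 ± 0.12, adjusted p = 1.5e-24). PR5 (AT1G75040), a thaumatin-like gene, was at 8.23 ± 0.37 against 1.52 ± 0.14, and PAD4 (AT3G52430), which acts upstream of salicylate, at 18.9 ± 1.0 against 8.08 ± 0.60. Floral MADS-box genes fell in 13 of 17 cases and rose in 1, the same adjusted over the list alone (median -0.27, adjusted p = 0.0091, but adjusted p = 0.13 with an estimated correlation). AG (AT4G18960), a stamen and carpel identity gene, was at 80.6 ± 2.9 against 106 ± 1.4 CPM. The boundary and meristem list had a median of 0.61 and was not called (adjusted p = 0.091, but 0.044 without WT replicate 2 and 0.041 with no filter). Of its 13 members 9 rose and 3 fell, the same adjusted over the list alone. KNAT1 rose from 52.7 ± 3.7 to 82.2 ± 2.3 CPM and LSH4 (AT3G23290) from 7.85 ± 1.1 to 14.5 ± 0.16. The flowering repressor gene FLM (AT1G77080) fell from 66.4 ± 1.9 to 28.4 ± 0.71 CPM, and TFL1 (AT5G03840), which delays flowering, rose from 1.66 ± 0.14 to 5.03 ± 0.76.

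At the top of the ranking within the expression limit, AT4G12735 had 0 counts in WT and was at least 189-fold higher in elf6-3ref6C, at 6.21 ± 0.063 CPM. AT4G07850, a transposable element gene, was at 6.76 ± 0.031 CPM against 0.034 ± 0.037, and AT2G03130, described as a ribosomal protein L12 relative, at 8.27 ± 0.98 against 0.0759 ± 0.011. The transporter gene AT2G04050 rose by 6.20 ± 0.19 and AT2G41730 by 5.97 ± 0.25 on the log2 scale. At the bottom within that limit, which leaves out STP11, were ELF6, AT3G05610 (-4.69 ± 0.18), AT1G72130 (-4.48 ± 0.18) and AT5G39880 (-4.44 ± 0.18), and AT3G53140, a methyltransferase gene that shares sequence with a neighbour, which was at 0.0309 ± 0.053 CPM against 11.7 ± 2.3.

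Compared with ref6C directly, elf6-3ref6C showed the same groups moving. Mature pollen genes fell in 13 of 18 cases and rose in 1 (median -1.70, adjusted p = 8.5e-06, and 0.011 with an estimated correlation), with VGD1 going from 258 ± 4.2 to 66.8 ± 1.1 CPM (SD, n = 3). Jasmonate genes fell in 18 of 25 cases and rose in 1 (median -0.48, adjusted p = 9.9e-06, and 0.0081 with an estimated correlation), with JAZ9 at 137 ± 2.7 against 225 ± 3.7 CPM. Anther and tapetum genes fell in 12 of 17 cases and rose in 2 (median -0.25, adjusted p = 0.0021, and 0.041 with an estimated correlation), with QRT3 at 67.2 ± 1.5 against 123 ± 1.9. Defence genes rose in 10 of 13 cases and fell in 0 (median 1.02, adjusted p = 2.8e-05, and 0.0496 with an estimated correlation). PR2 went from 2.48 ± 0.52 to 33.6 ± 1.5 CPM, WRKY70 from 19.3 ± 0.60 to 47.4 ± 1.4 and EDS1 (AT3G48090), a partner of PAD4, from 23.2 ± 1.2 to 47.1 ± 1.7. Floral MADS-box genes fell in 13 of 17 cases and rose in 0 (median -0.36, adjusted p = 0.00089, but adjusted p = 0.054 with an estimated correlation), SHP1 from 38.9 ± 1.9 to 24.9 ± 1.4. The counts adjusted over the list alone were the same except 13 anther genes falling and 1 floral MADS-box gene rising.

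Within the expression limit, the genes ranked highest in the step from ref6C to elf6-3ref6C were AT2G04050 (6.13 ± 0.19), AT4G07850 (5.45 ± 0.25), AT2G41730 (5.42 ± 0.23) and PNP-A (AT2G18660, 5.37 ± 0.24), which encodes a small secreted peptide. FLM fell by 1.16 ± 0.04, FLC (AT5G10140), another repressor of flowering, by 1.08 ± 0.09, and EXPA8 by 1.59 ± 0.06. SAG12, at 3.57 ± 0.51 CPM in ref6C, was at 0.033 ± 0.031 in elf6-3ref6C. AT3G53140 and ELF6 were at the bottom of the ranking within the limit. AT2G07739 and AT2G07080 were there only through ref6C replicate 3, where they were at 29.841 and 37.373 CPM against 0.681 and 0.71 and 1.431 and 1.352 in the others. Without it AT2G07739 changed by -0.92 in place of -4.80 and AT2G07080 by -0.33 (adjusted p = 0.19) in place of -3.57. In all 6873 genes were higher and 6848 lower than in ref6C, 742 and 1277 of them at least 2-fold (6468 and 6393, with 797 and 1215, without ref6C replicate 3).

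In elf6-3ref6Cjmj13G, pollen, anther and jasmonate genes were lower than in WT, and so were some floral MADS-box genes. AP3 (AT3G54340), a petal and stamen identity gene, was at 75.4 ± 1.4 CPM (SD, n = 3) against 171 ± 1.5 in WT (log2 fold change -1.18 ± 0.03, adjusted p = 5.6e-23), its partner PI (AT5G20240) at 164 ± 0.82 against 264 ± 8.6, and SEP2 (AT3G02310) at 113 ± 2.4 against 183 ± 1.4. The floral MADS-box list as a whole was not called (9 of 17 fell and 3 rose, the same adjusted over the list alone; median -0.20, adjusted p = 0.15). Mature pollen genes fell in 16 of 18 cases and rose in 0 (median -1.71, adjusted p = 1.8e-07, and 0.0059 with an estimated correlation). Anther and tapetum genes fell in 15 of 17 and rose in 1 (median -0.81, adjusted p = 5.3e-07, and 0.0059 with an estimated correlation). Of 25 jasmonate genes 21 fell and 2 rose (median -0.64, adjusted p = 5.3e-07, and 0.0059 with an estimated correlation). These counts were the same adjusted over the list alone. VGD1 was at 101 ± 1.5 CPM, MS2 at 182 ± 0.42, JAZ9 at 113 ± 3.2 against 271 ± 5.5 in WT, and MYB21 at 0.247 ± 0.049.

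Auxin genes and defence genes were higher in elf6-3ref6Cjmj13G than in WT. Of 10 auxin synthesis and transport genes 7 rose and 1 fell, the same adjusted over the list alone (median 0.47, adjusted p = 0.042, but adjusted p = 0.25 with an estimated correlation). The call also ended with a stricter filter (adjusted p = 0.052) and in a fit of the compared groups alone (0.063). The biosynthesis gene TAA1 (AT1G70560) rose from 35.9 ± 1.4 to 74.9 ± 3.7 CPM. Defence genes rose in 10 of 13 cases and fell in 1, the same adjusted over the list alone (median 0.43, adjusted p = 0.017, but adjusted p = 0.28 with an estimated correlation), with PR2 at 14.5 ± 0.36 CPM. Photosynthesis genes fell in 19 of 21 cases and rose in 2, the same adjusted over the list alone (median -0.27, adjusted p = 0.00064, but adjusted p = 0.57 with an estimated correlation). LHCA4 (AT3G47470) fell from 1280 ± 22 to 919 ± 19. The boundary and meristem list was not called (8 of 13 rose and 3 fell, the same adjusted over the list alone; median 0.41, adjusted p = 0.11). ALC (AT5G67110), a gene of fruit opening, rose from 48.2 ± 0.27 to 96.1 ± 1.3 CPM, and FLM fell by 1.60 ± 0.04.

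Within the expression limit, the genes ranked highest in elf6-3ref6Cjmj13G were mostly those of elf6-3ref6C: AT4G12735, at least 110-fold higher than in WT, AT4G07850 at 7.18 ± 1.0 against 0.034 ± 0.037 CPM, AT2G03130 (6.15 ± 0.23), AT2G38380 (5.45 ± 0.26) and AT5G35935 (5.33 ± 0.14). Those ranked lowest were BGAL13 (-6.77 ± 0.29), AT3G05610 (-6.18 ± 0.21), AT5G48140, a pectin lyase-like gene (-5.59 ± 0.17), MYB21 (-5.57 ± 0.21) and AT5G39880 (-5.37 ± 0.20). Across all genes called in both genotypes, 12962 had the same direction in elf6-3ref6C and elf6-3ref6Cjmj13G and 127 the opposite one; independent lists would share 2416 rising and 2688 falling genes. The correlation of fold changes across genes was 0.927. The covariance was 0.755, against 0.00919 in the simulation of unchanged groups, which was made for ref6-3 and ref6C and not for these genotypes.

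Fewer genes differed between elf6-3ref6Cjmj13G and elf6-3ref6C, 1923 higher and 2560 lower in the first, of which 94 and 197 were at least 2-fold (2092 and 2180, with 102 and 209, without ref6C replicate 3). ELF6 was 1.76 log2 units higher in elf6-3ref6Cjmj13G than in elf6-3ref6C, although both carry elf6-3. Changes in this step therefore cannot be put down to jmj13G alone. AP3 fell from 135 ± 1.2 to 75.4 ± 1.4 CPM (SD, n = 3), SEP2 by 0.56 ± 0.03 and PI by 0.50 ± 0.03. The floral MADS-box list as a whole was not called in this step, so these falls do not stand for the list. Jasmonate genes fell in 13 of 25 cases and rose in 2 (15 and 2 adjusted over the list alone; median -0.22, adjusted p = 1.3e-05, and 0.0082 with an estimated correlation). The cyclase gene AOC2 (AT3G25770) went from 17.9 ± 0.58 to 8.68 ± 0.29 CPM, MYB21 from 1.79 ± 0.20 to 0.247 ± 0.049, and VSP2 rose by 0.33 ± 0.02. Defence genes fell in 8 of 13 cases and rose in 0 (11 fell adjusted over the list alone; median -0.63, adjusted p = 6.3e-07, and 0.023 with an estimated correlation). PR2 fell from 33.6 ± 1.5 to 14.5 ± 0.36. Mature pollen genes rose in 6 of 18 cases and fell in 1, the same adjusted over the list alone (median 0.32, adjusted p = 0.00026, and 0.028 with an estimated correlation). VGD1 rose from 66.8 ± 1.1 to 101 ± 1.5. The anther and tapetum list was not called (2 rose and 2 fell of 17, the same adjusted over the list alone; median 0.01, adjusted p = 0.81).

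FT (AT1G65480), the mobile promoter of flowering, rose from 0.501 ± 0.097 CPM in elf6-3ref6C to 2.73 ± 0.21 in elf6-3ref6Cjmj13G (log2 fold change 2.45 ± 0.22, adjusted p = 2.5e-09), while it was at 0.667 ± 0.16 CPM in WT. In the auxin list 3 of 10 genes rose and 0 fell (5 rose adjusted over the list alone; median 0.11, adjusted p = 0.0099, but adjusted p = 0.13 with an estimated correlation), TAA1 by 0.49 ± 0.04. Photosynthesis genes fell in 15 of 21 cases and rose in 0 (17 fell adjusted over the list alone; median -0.13, adjusted p = 5.0e-07, but adjusted p = 0.36 with an estimated correlation). LHB1B1 fell by 1.45 ± 0.07. AT2G01422 fell from 24.8 ± 1.6 to 1.37 ± 0.19, BGAL13 by 2.38 ± 0.56 and the subtilase gene SBT4.13 (AT5G59120) from 2.37 ± 0.69 to 0.52 ± 0.15 CPM. Within the expression limit, which leaves out FT, the genes ranked highest beside ELF6 were GPT2 (AT1G61800), a plastid sugar phosphate transporter gene, from 12.2 ± 0.40 to 40.2 ± 1.8 CPM, AT3G53140, from 0.0309 ± 0.053 to 2.35 ± 1.1, and CPuORF31 (AT1G48598), which had 0 counts in elf6-3ref6C and was at least 334-fold higher. The last of these is a short upstream reading frame that the annotation used does not list. Its counts came and went within a genotype (25.934, 0 and 9.807 CPM in the WT libraries, 0, 0 and 9.778 in ref6C), and the bound covers counting error only, so its rise is uncertain.

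**Figure D3:**
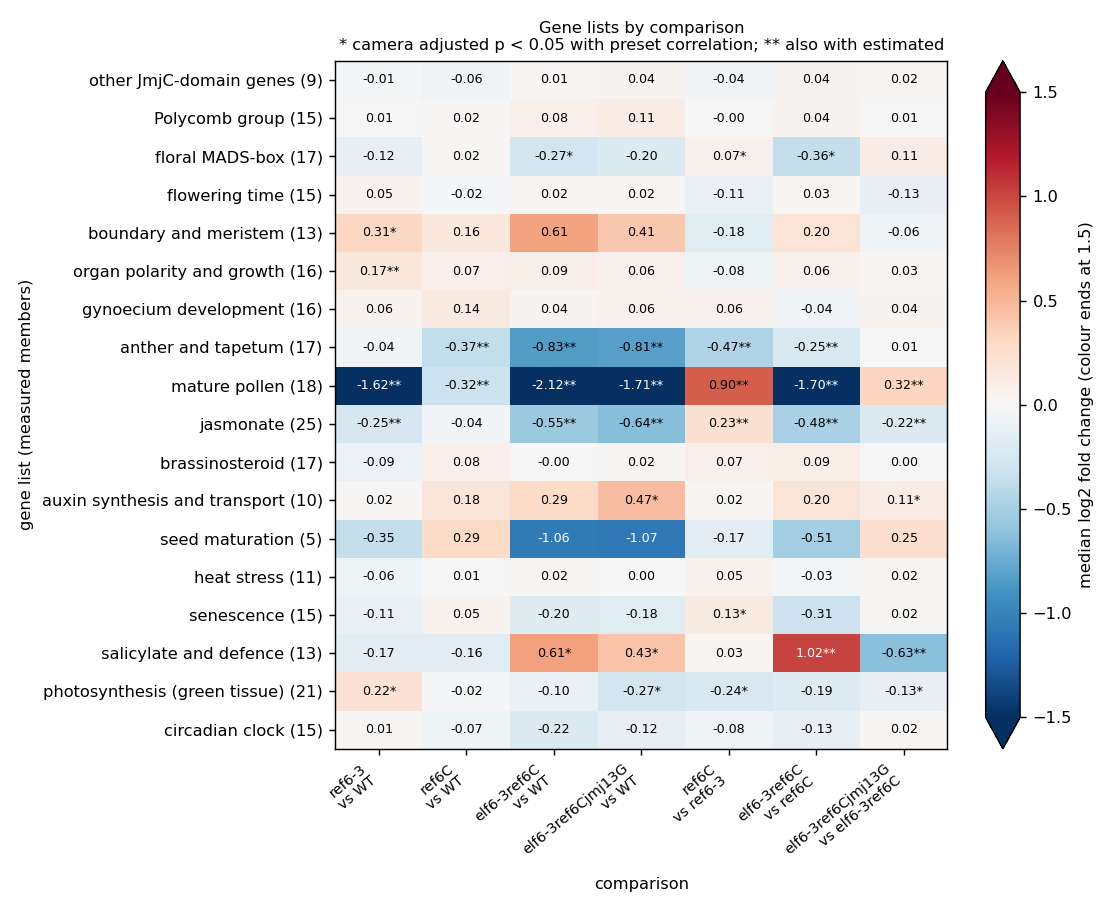
Median log2 fold change of each gene list (vertical axis, measured members in brackets) in each comparison (horizontal axis); an asterisk marks a camera adjusted p below 0.05 and a double asterisk one that also holds with an estimated correlation. Mature pollen genes are low in ref6-3 (-1.62), elf6-3ref6C (-2.12) and elf6-3ref6Cjmj13G (-1.71), and anther and tapetum genes in the genotypes with ref6C (-0.37, -0.83 and -0.81).

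Genes that fell with REF6 alone mostly fell in the multiple mutants. Of the 1119 genes at least 2-fold lower in ref6-3, 986 were at least 2-fold lower in elf6-3ref6C and 924 in elf6-3ref6Cjmj13G, where independent lists would share 111 and 113. The multiple mutants carry ref6C: of the 749 genes at least 2-fold lower in ref6C, 572 and 592 were (74.4 and 75.5 for independent lists). Called in the opposite direction were 23 and 26 of the ref6-3 genes and 32 and 14 of the ref6C genes. Of the 446 lower in both REF6 mutants, 405 and 399 were at least 2-fold lower in elf6-3ref6C and elf6-3ref6Cjmj13G (44.3 and 45.0 for independent lists), with medians of -2.81 and -2.79. Of the 75 higher in both, 65 and 63 were at least 2-fold higher. For the 152 genes higher in ref6-3 these counts were 106 and 91, and for the 268 higher in ref6C 168 and 149. These counts rest on comparisons that share the WT libraries. The step that adds elf6-3 does not use WT and went the same way. The 4145 genes lower in ref6-3 had a median of -0.38 in elf6-3ref6C over ref6C (adjusted p = 2.3e-24, and 9.8e-09 with an estimated correlation), and the 3632 genes higher in ref6-3 a median of 0.15 (adjusted p = 3.8e-10, and 0.00032). From elf6-3ref6C to elf6-3ref6Cjmj13G the sets moved slightly the other way, by 0.06 for the lower set (adjusted p = 8.9e-09, and 1.2e-06) and -0.06 for the higher set (adjusted p = 2.4e-08, and 0.00066). ELF6 transcript also rose in that step (log2 fold change 1.76), so the shift cannot be put down to jmj13G alone. These sets come from the same libraries of ref6-3 and WT and were not fixed beforehand. The step that adds elf6-3 starts from ref6C, whose mature pollen transcripts were above those of ref6-3 (list median log2 fold change 0.90). Pollen transcript lost in that step may thus make up part of the shift, which was not tested.

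**Figure D4:**
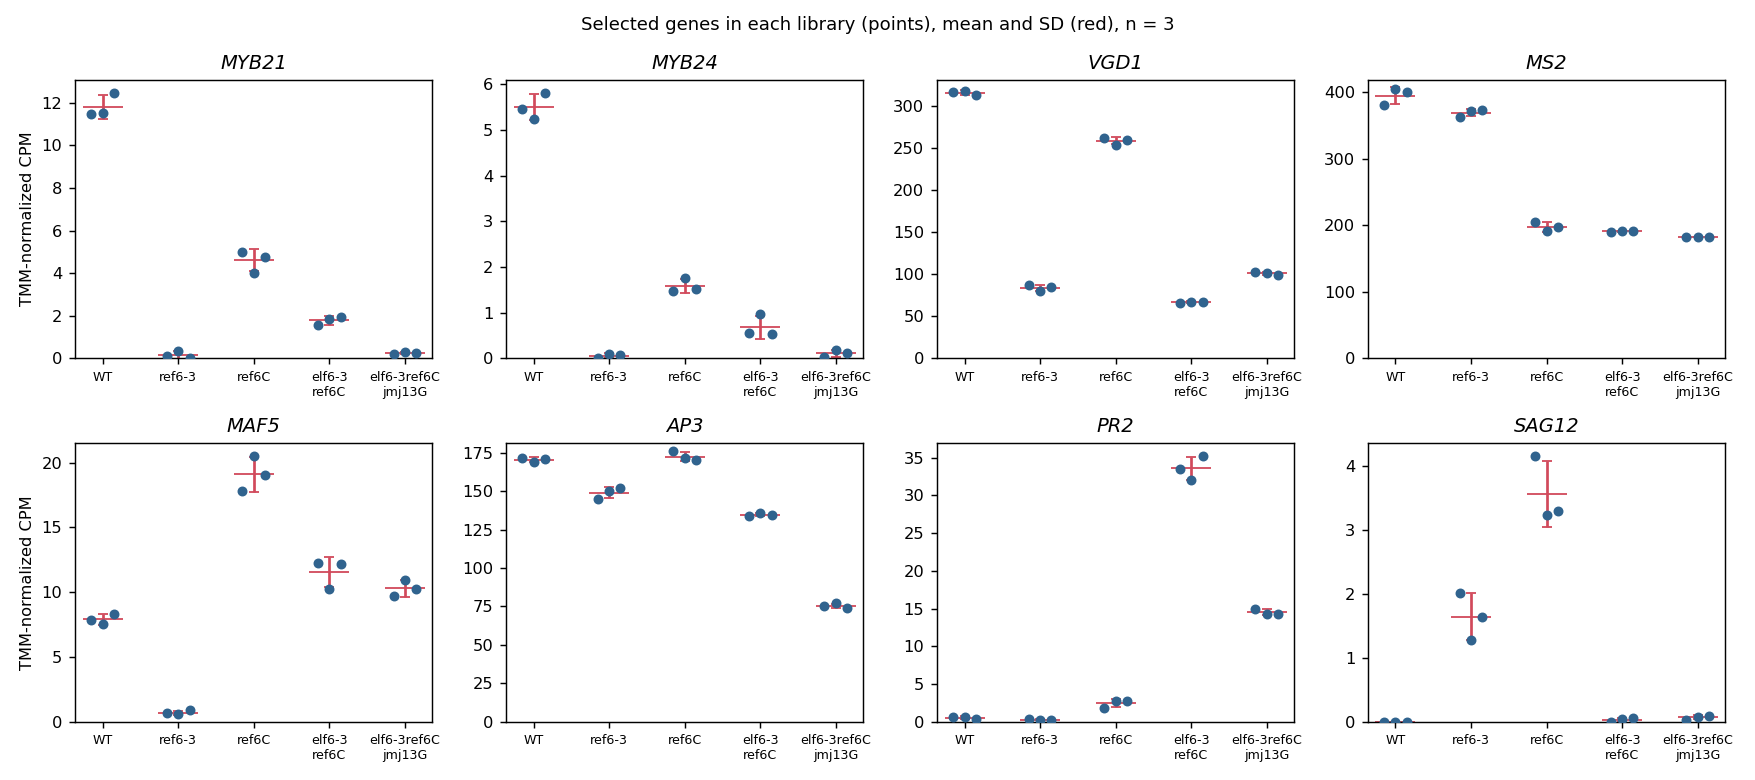
TMM-normalized CPM of MYB21, MYB24, VGD1, MS2, MAF5, AP3, PR2 and SAG12 in each library (points) with the mean and SD of each genotype (red, n = 3). MYB21 is at 11.8 CPM in WT and 0.152 in ref6-3, MAF5 at 0.70 in ref6-3 and 19.1 in ref6C, AP3 lowest in elf6-3ref6Cjmj13G at 75.4 and PR2 highest in elf6-3ref6C at 33.6.

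Of the 18 lists, 8 were called in no comparison. Camera gave adjusted p-values between 0.11 and 0.97 in their 56 tests, with 1 unadjusted p below 0.05, and 0 below 0.05 with an estimated correlation (lowest adjusted p = 0.25). With no filter the circadian clock list was called in ref6C against ref6-3 (adjusted p = 0.031). The medians of these 8 lists over the 7 comparisons ranged between -0.06 and 0.04 for the other JmjC-domain genes, 0.00 and 0.11 for the Polycomb group, -0.13 and 0.05 for flowering time, -0.04 and 0.14 for gynoecium development, and -0.09 and 0.09 for brassinosteroid. The ranges were -0.06 and 0.05 for heat stress, -0.22 and 0.02 for the circadian clock, and -1.07 and 0.29 for seed maturation, where 5 members were measured. Single members were called all the same, and those with the smallest adjusted p are named here. Against WT, 68.5% of all tested genes were called in elf6-3ref6C and 34.7% in ref6-3, so called members do not set these lists apart. The demethylase relative JMJ22 (AT5G06550) rose in elf6-3ref6C by 0.85 ± 0.05, the Polycomb-associated gene EMF1 (AT5G11530) by 0.57 ± 0.03, and the cold-induced gene VIN3 (AT5G57380) fell by 1.05 ± 0.10. The seed regulator genes AGL15 (AT5G13790) and FUS3 (AT3G26790) fell there by 1.06 ± 0.09 and 1.41 ± 0.19. The clock gene ELF4 (AT2G40080) rose by 0.85 ± 0.06. The heat shock genes HSP90.1 (AT5G52640) and HSP70 (AT3G12580) fell by 0.33 ± 0.06 and 0.28 ± 0.07 in ref6-3, and the carpel gene CRC (AT1G69180) rose there by 0.25 ± 0.03.

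The authors' deposited table of statistics held fewer calls with the same directions. At an adjusted p below 0.05 it had 2648 genes higher and 3077 lower in ref6-3 than in WT, 2427 and 3109 in ref6C, 6816 and 6912 in elf6-3ref6C, and 6466 and 6778 in elf6-3ref6Cjmj13G. At least 2-fold changed were 40 higher and 777 lower, 69 and 470, 546 and 1470, and 386 and 1447 in the same order, all below the 2-fold counts found here. Without ref6C replicate 3, which the authors left out, the 2-fold counts here were 206 and 838 in ref6C. DESeq2 run here gave 138 and 1092 in ref6-3, also above the deposited counts. How the deposited fold changes were scaled is not given in the sources used here, so 2-fold may not mean the same in both. Genes called both in the authors' deposited table and by edgeR here numbered 5623, 5437, 13415 and 12981 in these comparisons, with 0 in opposite directions. Fold changes in the authors' deposited table correlated across genes with those found here at 0.889, 0.881, 0.916 and 0.908.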

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

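Of the 18 gene lists, 6 differed between ref6C and ref6-3 in a direct test of one mutant against the other, which is why they are set out here. The test of ref6C replicate 3 below was chosen only after the result was seen. Median log2 fold changes of ref6C over ref6-3 were 0.90 for mature pollen, -0.47 for anther and tapetum, 0.23 for jasmonate, 0.135 for senescence, 0.069 for floral MADS-box and -0.24 for photosynthesis genes. With an estimated correlation the calls for senescence, floral MADS-box and photosynthesis were lost (adjusted p = 0.20, 0.23 and 0.30).

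The library with counts in more genes, ref6C replicate 3, is excluded as the whole source of the 2-fold differences: 965 genes still differed at least 2-fold without it, against 1004 with it. That count does not test the lists. Without the library the senescence list call ended (camera adjusted p = 0.088), and the other list calls held. A lower share of mature pollen in the ref6-3 buds could account for part of the difference between the REF6 mutants. Against ref6C, 782 genes were at least 2-fold lower in ref6-3, and 586 of these (74.9%) also in elf6-3ref6C. Independent lists would share 5.70%. The share was short of the 80% set as a bound and far above 20%. Both comparisons rest on the same ref6C libraries, which adds to the overlap. The count was not limited to pollen genes, and any gene higher in ref6C than in both other genotypes enters it. It therefore cannot tell a pollen share from other causes, and this stays open. Anther and tapetum genes, lower in ref6C, moved against the pollen genes. The REF6 transcript was 0.14 log2 units higher in ref6C than in ref6-3, a call that ended when any of 4 libraries was left out. Different effects of the alleles on the REF6 protein stay open and untested. The labels do not describe the alleles.

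For each comparison the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split ranked as number 1 in every comparison. Every other split puts libraries of both genotypes in each group, so the difference between genotypes counts there as spread. Few calls in those splits follow from this make-up and say nothing of the rate of false calls. edgeR called 7777 genes in ref6-3 against WT, and at most 0 in the other splits (1463 at an unadjusted p below 0.05). The counts were 8705 and 0 (1775) for ref6C, 15359 and 0 (882) for elf6-3ref6C and 14887 and 0 (1071) for elf6-3ref6Cjmj13G against WT. They were 7603 and 0 (1109) for ref6C against ref6-3, 13721 and 0 (836) for elf6-3ref6C against ref6C, and 4483 and 1 (1191) for elf6-3ref6Cjmj13G against elf6-3ref6C. DESeq2 was not run on the splits.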

How the results depend on the processing

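Of the alternatives below, leaving ref6C replicate 3 out of comparisons without ref6C was chosen only after the data were seen. With an estimated correlation 21 list tests were called in place of 34. Genes at least 2-fold higher than in WT numbered 95 in ref6-3 (152) and 159 in ref6C (268) with a filter of 1 CPM in 3 libraries, which tests 20629 genes, and 571 in ref6C with no filter, which tests 31007. ELF6 in ref6C over ref6-3 was -0.10 (adjusted p = 0.039) with no filter, against -0.09 (0.075); the cause was not tested. With single replicates left out, ELF6 in ref6C over WT ranged from -0.12 to -0.10 and lost its call without ref6C replicate 2 or 3 or WT replicate 1 or 2, and REF6 in ref6C over ref6-3 ranged from 0.11 to 0.16 and lost its call without replicate 1 or 2 of ref6-3 or 2 or 3 of ref6C. Fewer libraries were tested in each of these. List calls numbered 33 to 35 over these sets, and calls shared by the REF6 mutants 3427 to 3837 (4032 with all libraries). For the named genes, 5264 alternative values in 420 pairs of gene and comparison gave 20 lost calls in other settings, 14 of them with DESeq2, 52 lost calls with a replicate left out, and 0 changes of direction.

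The replicate number as a block gave 3480 higher and 4046 lower genes in ref6-3, 4015 and 4470 in ref6C, 7483 and 7732 in elf6-3ref6C and 7115 and 7640 in elf6-3ref6Cjmj13G against WT. It gave 1843 and 2390 in elf6-3ref6Cjmj13G against elf6-3ref6C. It ended the list calls for auxin in elf6-3ref6Cjmj13G against WT and floral MADS-box in ref6C against ref6-3 (adjusted p = 0.053 in each). Same-numbered libraries did not deviate together (correlations -0.275 to 0.231), so the numbers do not pair them. DESeq2 called 3203 and 3365 genes in ref6-3 and 3450 and 3820 in ref6C, with 0 calls opposite to edgeR. Leaving out organelle genes was not run, because the deposited table holds 0 of them.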

Other observations

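The families named here were tested and chosen only after the values were seen. Genes were grouped by their description in the annotation, and each of 142 families with at least 15 tested members was compared with the genes at least 2-fold changed (Fisher's test, adjusted over 1136 tests). Families described by pectin or by invertase were over-represented among the lower genes, except pectin lyase-like genes in ref6C. A description does not tell enzymes from inhibitors. Of 41 genes described as invertase or pectin methylesterase inhibitor superfamily proteins 21 were at least 2-fold lower in ref6-3 (2.05 for independent sets, adjusted p = 1.1e-14), 8 in ref6C (0.0024), 22 in elf6-3ref6C (4.1e-10) and 23 in elf6-3ref6Cjmj13G (5.9e-11). A further 25 genes carry nearly the same description, and 10 (1.4e-05), 6 (0.0051), 11 (0.00058) and 11 (0.00064) of them were lower in the same order. Of 69 pectin lyase-like genes 15 fell in ref6-3 (8.6e-05), 6 in ref6C (0.34), 24 in elf6-3ref6C (2.3e-06) and 19 in elf6-3ref6Cjmj13G (0.0017). VGD1, PPME1, AT3G05610 and AT5G48140 carry descriptions of these families.

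F-box families were over-represented among the lower genes of elf6-3ref6C and elf6-3ref6Cjmj13G. Of 89 genes described with an F-box and an associated interaction domain, 36 were at least 2-fold lower in elf6-3ref6C (adjusted p = 5.9e-12) and 45 in elf6-3ref6Cjmj13G (6.5e-19), against 4 in ref6-3 (1.0) and 8 in ref6C (0.17). Of 30 genes of the F-box, RNI-like and FBD-like class the counts were 15 (3.2e-06), 13 (0.00016), 3 (0.99) and 4 (0.25) in the same order. Whether the genotypes differ in these shares was not tested. Peroxidase genes were more frequent among risen genes than in independent sets: of 41, 4 were at least 2-fold higher in ref6-3 (0.0058), 5 in ref6C (0.0047), 11 in elf6-3ref6C (2.0e-05) and 6 in elf6-3ref6Cjmj13G (0.033). In the same order 4, 2, 4 and 8 were at least 2-fold lower (0.90, 1.0, 1.0 and 0.51), so in elf6-3ref6Cjmj13G more of them fell than rose. Of 296 transposable element genes 10 rose in ref6-3 (0.0017), 28 in ref6C (1.1e-14), 50 in elf6-3ref6C (1.9e-16) and 41 in elf6-3ref6Cjmj13G (6.9e-14), while 31, 13, 55 and 62 fell (0.0037, 1.0, 0.00022 and 2.3e-06). Without ref6C replicate 3, 12 of 302 rose in ref6C (2.75 for independent sets, unadjusted p = 2.3e-05). Genes of a family are not independent, so these p-values are too small.

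The following tests were chosen only after the result was seen: reads of other libraries as the source of the added genes in ref6C replicate 3, and younger buds as the source of the lower pollen transcripts. The ref6C replicate 3 library had counts in 29547 genes against at most 25712 in the others. Among 4048 genes with no count in the other 14 libraries, 3739 had a length in the annotation; 1703 of them had a count there, and the count rose with exon length (Spearman rho 0.730, highest of 200 permutations 0.0425), so genomic DNA in the library may be the source, at about 0.298% of its counts. RNA of another tissue is argued against, since the 10 top genes held only 5.00% of those counts, and so are reads of the other 14 libraries, since 1732 genes had a count in this library alone against 21 to 56 in each of the others. DNA of the sample and DNA from other libraries of the same run were not told apart by any test. Low transcription of every gene would look alike. Among the genes without a count elsewhere, counts per kb were uneven, at 1.07 in protein-coding and 1.55 in pseudogene or transposable element genes. They ran from 0.321 in the shortest genes to 1.60 in the longest, while the share given takes even coverage. AT2G01008, AT2G07739 and AT2G07080, far higher in this library, had counts in others, so the test does not cover them. No effect of the ref6C mutation was tested as an explanation, since the other ref6C libraries did not show the pattern.

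Lower mature pollen transcripts in all mutants could come from younger buds in the sample or from an effect of the mutations on pollen. Younger buds should hold more transcript of boundary and meristem genes. In ref6-3 that list was higher (median 0.31, camera adjusted p = 0.0052, but 0.085 with an estimated correlation) while the anther and tapetum list had a median of -0.04. That is the pattern the test set for younger buds. An effect on mature pollen alone could also leave the anther and tapetum list unchanged, so the match does not favour younger buds. In ref6C, elf6-3ref6C and elf6-3ref6Cjmj13G the boundary and meristem list had medians of 0.16, 0.61 and 0.41 and was not called (camera adjusted p = 0.18, 0.091 and 0.11). Anther and tapetum genes were lower there (-0.37, -0.83 and -0.81). An earlier form of the test took this to exclude younger buds, but buds younger than the tapetum stage would lower those genes too. The explanation thus stays open. An effect of the mutations on anthers or pollen is open as well and was not tested, since stage and genotype cannot be separated here.

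Direct action of REF6 is a candidate explanation for the genes lower in both REF6 mutants, and was tested with its binding motif CTCTGYTY, named before the data were examined. The 444 such genes with a sequence held 0.657 matches per kb in the gene and 1000 bp upstream, against a median of 0.406 in 1000 sets matched on expression and length, a ratio of 1.62 that was above 100% of the sets. Of 20 shuffled motifs, 0 reached that ratio, but their ratios ran from 0.935 to 1.54. Shuffled motifs can still resemble the real one, so how much of the excess reflects base composition cannot be told. Expression was matched on the mean over all 15 libraries, mutants included, and the tissue of expression was not matched. An excess that genes of pollen or anthers hold in general would therefore look alike. The 75 genes higher in both had 0.353 matches per kb against 0.417 (ratio 0.847), with 10.8% of the matched sets below them. The motif was counted in sequence, and binding was not analysed here.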
